A study of Mus musculus with 198 samples.

How the data were processed

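The series covers mouse embryonic stem cells with single or combined losses of PRC2 and PRC1. Its 96 RNA libraries were used, and its 102 ChIP-seq samples were not analysed here. Per the labels' protocols, libraries were QuantSeq 3′ mRNA sequencing of cells grown feeder-free in serum and leukaemia inhibitory factor, with 250 µM auxin where given. The deposited counts were made with slamdunk 0.2.4 on mm10 over a custom annotation of 3′-end windows, per the file headers, which name 1 annotation. The deposited CPM values, also per the file headers, scale the reads of each window by library size. They were not used further, and CPM in the text was computed from the counts with TMM-scaled library sizes. Columns for T-to-C conversions held 0 such reads. The submitters' processing notes also name Bowtie2, DESeq2, MACS2, SAMtools and deepTools without versions or roles, and whether strand was used is not given in the sources used here. No exon annotation was used.

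Counts of the 28568 windows (median length 250) were summed to 22281 gene names, of which 21844 match an Ensembl table and 4656 have several windows. Positions are those of a gene's window, or of its window with most reads. Windows of 493 genes overlap another gene's window on the same strand and of 811 on the other strand. Reads in windows made up 58.57 to 68.43% of library reads, multimapping reads 17.45 to 20.5% and the 10 largest genes 6.22 to 8.02%. Depth per line is in the report.

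Genes were kept by filterByExpr with a minimum count of 10 (10265 tested, 12016 removed). Counts were fitted with edgeR 4.0.16 (glmQLFit with legacy = FALSE, glmQLFTest, TMM scaling, R 4.3.3) over all 96 libraries with 1 coefficient per group (64 residual degrees of freedom). TMM factors were 0.935 to 1.07, the negative binomial dispersion 0.00507 and the median prior degrees of freedom 42.4. P-values were adjusted by Benjamini and Hochberg within a contrast and a gene was called at adjusted p < 0.05. The 30 contrasts were each null line against wild-type at 0 h, auxin in each line without a degron, each degron genotype at 6, 24 and 48 h against 0 h, the 48 h effect beyond that of the parental null line, differences of 48 h effects between genotypes and between clones, degron clones before auxin against the parental line, and the combined loss at 48 h less both single losses. Degron contrasts average the effects of both clones. Standard errors were computed from the fitted counts, the negative binomial dispersion and the quasi-likelihood dispersion of each gene.

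A ratio against a group with 1 to 3 counts is given with its counting interval. Against 0 counts it is given as a lower bound that sets 3 counts over the group's libraries. The targeted genes were named in every group. For null lines against wild-type, 48 h degron effects and the combined losses, the rule allowed the 8 largest rises and 8 largest falls with adjusted p < 0.05, at least 5 CPM in the highest group and no overlap between libraries, and 3 and 3 for other contrasts. From each list up to 4 members with the smallest adjusted p could be named, and any member beside a count of its list. Some genes that the rule allows are not reported here.

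The 20 gene lists held, as genes listed and tested, PRC2 (12, 12), canonical PRC1 (12, 11), variant PRC1 (18, 17), naive (20, 19), core (12, 12), formative and primed pluripotency (13, 11), primitive endoderm (23, 16), mesoderm and primitive streak (34, 13), neural and ectodermal regulators (52, 18), Hox clusters (39, 20), trophectoderm (21, 15), germline and meiotic genes (32, 28), 2-cell-like genes (26, 14), cell cycle inhibitors (7, 5), p53 targets (19, 19), aryl hydrocarbon receptor targets (10, 3), imprinted genes (26, 20), fibroblast or feeder markers (15, 5), haematopoietic and endothelial markers (14, 1) and ribosomal protein genes (41, 41). They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists and contrasts of a family, and again with an estimated correlation and with fry. Lists with under 5 tested genes had no camera test. Genes of a list were also adjusted over the list alone.

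Alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, the libraries of a contrast fitted alone, a replicate block, each library left out in turn, each clone alone, single nulls at 0 h, reads not multimapping, no genes of chromosomes 6, 8, 14 and X, both doubted libraries left out, and subunit lists without the gene deleted in the line. The last 4 were added after the data were examined. Libraries were also regrouped in up to 100 ways per contrast and fitted alone. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

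Sensitivity was tested on simulated data made from these counts. The changed genes were drawn from those averaging at least 5 CPM over all libraries, so the shares do not cover genes below that level. With 3 against 3 libraries 35.8, 73.1 and 90.9% of 1.5-, 2- and 4-fold changes were called and 7 genes were called falsely. With 6 against 6 it was 62.7, 94 and 100%, with 18 false calls. A count table was also checked for duplicated libraries (chi-square per degree of freedom 1.099 to 8).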

Results

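RNA was measured by 3′ mRNA sequencing (QuantSeq), which reads the end of each transcript, in mouse embryonic stem cells grown without feeders in serum and leukaemia inhibitory factor. The 96 libraries formed 32 groups of 3. Wild-type cells and lines lacking Eed, Rybp or Ring1 were each sampled at 0 h and after 48 h of 250 µM auxin. In 3 further genotypes 1 protein carried an auxin-inducible degron, a tag that sends it to the proteasome when auxin is added: Rybp in Eed-null cells (clones A12 and C3), Suz12 in Rybp-null cells (A8 and B11) and Rnf2 in Ring1-null cells (B10 and C2). These clones were sampled at 0, 6, 24 and 48 h of auxin. Eed and Suz12 are core subunits of PRC2, the histone H3 methyltransferase complex. Rybp belongs to variant PRC1, and Ring1 and Rnf2 are the alternative ubiquitin ligase subunits of every PRC1. The degron lines therefore combine loss of a PRC2 core subunit with loss of Rybp, or loss of both ligase subunits. Whether a complex was lost was not measured in these data. The 102 ChIP-seq samples of the series were not analysed here.

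Reads in 3′-end windows ranged from 234252 to 3892707 per library (median 1326598) and 9922 to 13917 genes were detected. By line the ranges were 234252 to 1321472 in wild-type, 784408 to 1647749 in Eed-null, 929849 to 1881161 in Rybp-null and 799494 to 2402546 in Ring1-null cells. They were 953691 to 3892707 in A12, 705215 to 1637621 in C3, 851056 to 1882346 in A8, 651945 to 2667928 in B11, 1040159 to 2093370 in B10 and 1089180 to 3294104 in C2. Of 22281 gene names, 10265 were tested. Each null genotype was 1 clonal line, so line and genotype cannot be separated. The labels do not say whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples. Intervals on ratios cover counting error only. Gene lists, tests and comparisons were fixed before the data were examined. Genes named by the rule given above with a fold change kept direction and call in every alternative analysis unless an exception is given, and every camera call held with an estimated correlation unless a second p is given.

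The targeted genes came first, to see which losses were visible in RNA. Eed (chr7:89954654–89954978), which binds methylated H3 within PRC2, averaged 288.3 ± 20.3 CPM in wild-type and 5.112 ± 1.77 CPM in Eed-null cells (mean ± SD, n = 3), and 1.921 to 3.536 CPM in the 8 groups of Rybp-degron clones. Rybp (chr6:100228564–100228814), the variant PRC1 adaptor, averaged 140.4 ± 1.26 CPM in wild-type and 0.2666 ± 0.462 CPM in Rybp-null cells, and at most 1.232 CPM in Suz12-degron clones. In the clones carrying the Rybp degron it stood at 192.8 ± 2.64 CPM in A12 and 13.14 ± 0.589 CPM in C3 at 0 h, and at 209.3 ± 20.1 and 14.07 ± 3.31 CPM at 48 h. Of its reads, 99.6% mapped to several places, so its exact levels are uncertain. Its near absence in Rybp-null cells (1 count at 0 h, against 398 in wild-type) argues against reads from other places making up its wild-type level. Suz12 (chr11:80033644–80034123), the PRC2 scaffold, averaged 87.03 ± 3.45 CPM in wild-type, 92.3 ± 10.3 (A8) and 105.7 ± 33.3 CPM (B11) at 0 h and 68.18 ± 14.2 and 94.49 ± 6.39 CPM at 48 h. Rnf2 (chr1:151469406–151469776), the main PRC1 ligase, averaged 190.5 ± 21.2 CPM in wild-type, 236.6 ± 27.2 (B10) and 212.7 ± 14.6 CPM (C2) at 0 h and 186.1 ± 22.9 and 192.4 ± 5.23 CPM at 48 h. Ring1 (chr17:34021087–34021336), its paralogue, stayed at or below 1.677 CPM in every group, was not tested, and its loss could not be checked. A 3′ tag outside a deleted part checks nothing about a deletion, and RNA does not report the degradation of a tagged protein.

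**Figure D1:**
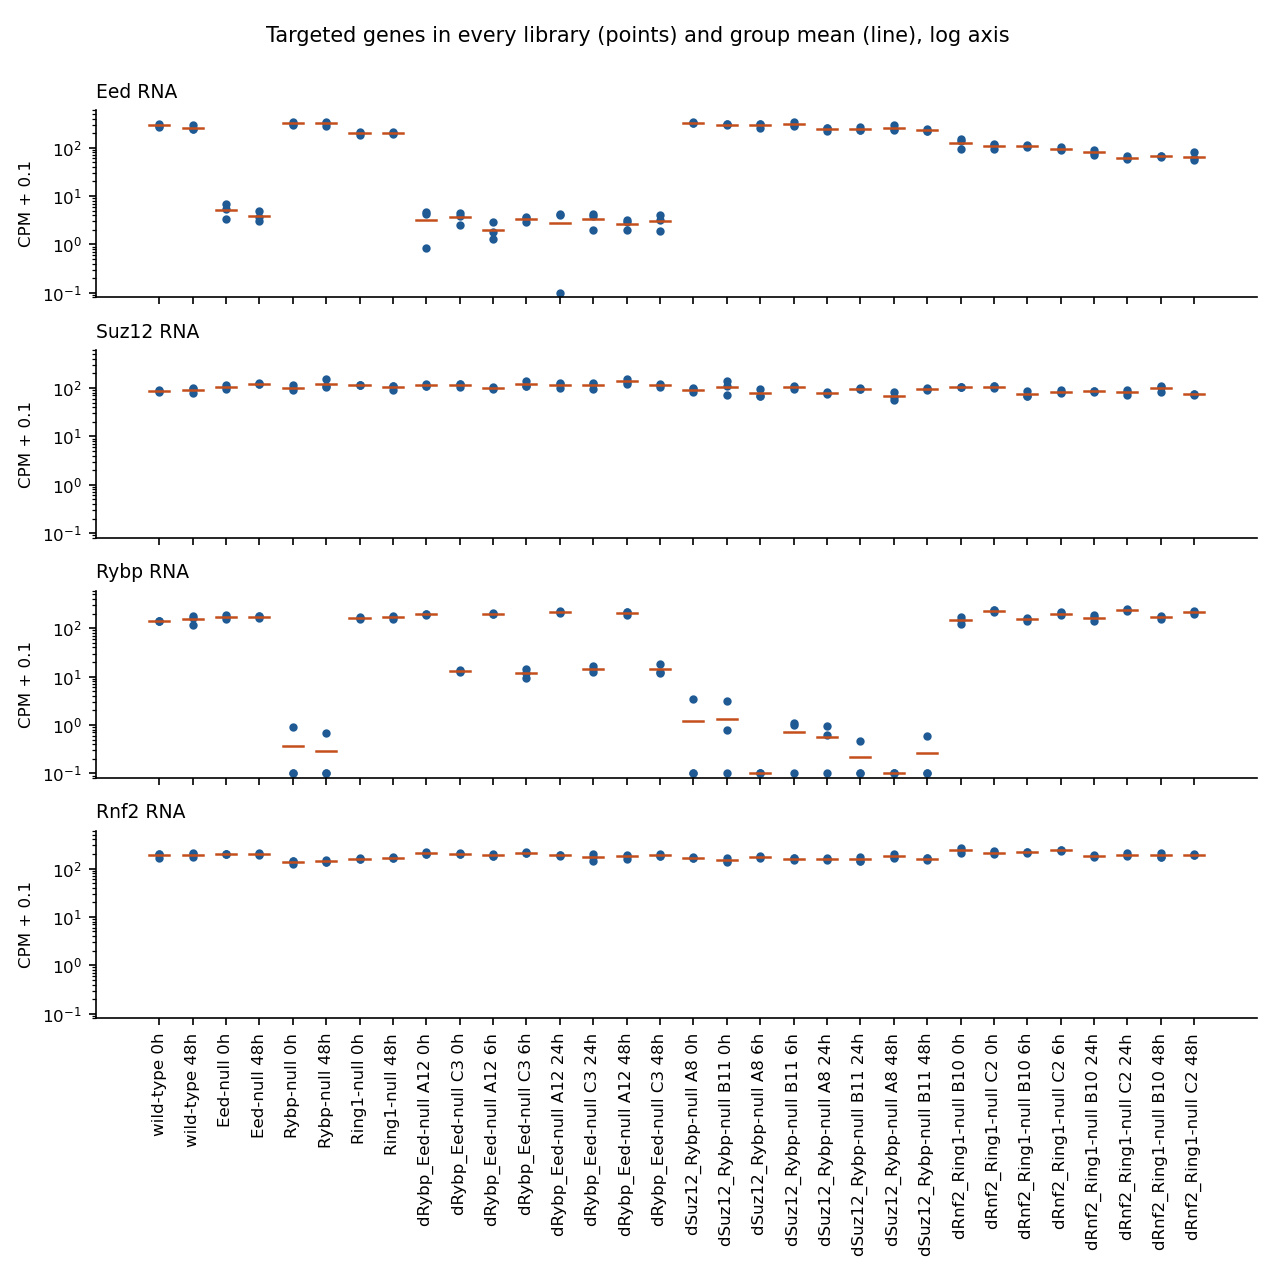
CPM plus 0.1 (log axis) of Eed, Suz12, Rybp and Rnf2 in each library, by line and hours of auxin. Points are libraries and horizontal lines are means of 3.

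To ask what loss of Eed changed, Eed-null cells were compared with wild-type cells at 0 h (3 against 3). Hox genes, the positional regulators of the body axis, rose from near absence. Hoxa10 (chr6:52231197–52231446) rose 57.9-fold (interval 10.1 to 2.32e+03), Hoxa11 (chr6:52242105–52242354) 34.4-fold (5.87 to 1.39e+03), Hoxd13 31.3-fold (5.31 to 1.27e+03). Hoxa9 (chr6:52223097–52223346) rose at least 7.57-fold from 0 counts. Of 20 Hox genes tested, 10 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 6.95e-13). Primitive endoderm genes rose as well (7 and 0 of 16, 11 and 1 adjusted over the list alone, adjusted p = 1.55e-09). Gata4 (chr14:63198914–63199163), an endoderm master regulator, rose 17.2-fold (2.78 to 711). The basement membrane genes Col4a1 (chr8:11198423–11198672) and Lamb1 rose by log2 1.38 ± 0.19 and 1.27 ± 0.25 (± SE). Cited1, a transcriptional co-activator, rose by 2.17 ± 0.43. The formative regulator Otx2 (chr14:48657677–48657928) rose from 49.1 ± 6.38 to 123.7 ± 13.4 CPM (log2 1.32 ± 0.17, adjusted p = 3.3e-10). The formative and primed list had 2 higher and 0 lower of 11 (2 and 0 adjusted over the list alone, adjusted p = 4.68e-05).

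Trophectoderm genes rose in the same Eed-null cells (5 and 0 of 15, 7 and 0 adjusted over the list alone, adjusted p = 4.68e-05). Among them were the placental regulator Tfap2c (log2 0.99 ± 0.20) and the epithelial genes Elf3 (0.61 ± 0.13) and Krt19 (1.97 ± 0.57). Mesoderm and primitive streak genes had 4 higher and 0 lower of 13 (4 and 0 adjusted over the list alone, adjusted p = 0.0118), including the heart regulator Tbx5 (3.05 ± 0.72). Imprinted genes had 2 higher and 1 lower of 20 (5 and 3 adjusted over the list alone, adjusted p = 0.0334), with H19, a maternally expressed noncoding RNA, at 1.43 ± 0.27. Against 16.5 ± 3.99 CPM in wild-type, H19 stood at 2.127 ± 0.672 in A12 and 180.5 ± 9.39 CPM in C3 at 0 h, clones that also lack Eed. Genes that fell included Pramel7 (chr2:87489085–87489338), expressed in the inner cell mass, by 28.5-fold (9.35 to 142), the naive marker Fbxo15 (−0.74 ± 0.12) and the testis tubulin Tuba3a (−1.67 ± 0.25). Naive pluripotency genes had 0 higher and 2 lower of 19 (0 and 4 adjusted over the list alone, adjusted p = 0.161). Core pluripotency genes had 0 of 12 (0 adjusted over the list alone, adjusted p = 0.689). In the PRC2 list of 12, 1 gene rose and 2 fell, Eed among them (2 and 3 adjusted over the list alone). Its median was 0.06, its mean −0.26 and its camera test pointed down (adjusted p = 0.000466), but this rested on the deleted Eed. Without it the other 11 genes had a median of 0.12, a mean of 0.25 and no list call (adjusted p = 0.706). The p53 targets had 2 higher and 0 lower of 19 (2 and 1 adjusted over the list alone) while their test pointed down (adjusted p = 0.201). Neural (3 and 2 of 18), germline (4 and 3 of 28), cell cycle inhibitor (1 and 0 of 5) and fibroblast genes (0 and 1 of 5) passed no test (adjusted p = 0.0567, 0.689, 0.228 and 0.468). Adjusted over the list alone these 4 lists had 8 and 2, 6 and 3, 1 and 0, and 3 and 1. Variant and canonical PRC1, 2-cell-like, ribosomal protein, aryl hydrocarbon receptor and haematopoietic lists had 0 calls.

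In total 315 genes were higher and 205 lower in Eed-null cells by edgeR quasi-likelihood F-test at adjusted p < 0.05 (133 and 77 by at least 2-fold). The 520 calls fell to 338 without Eed-null 0 h replicate 1 and to 340 without replicate 2.

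The effect of losing Rybp was examined by comparing Rybp-null with wild-type cells at 0 h (3 against 3). Germline and meiotic genes rose (18 and 0 of 28, 21 and 1 adjusted over the list alone, adjusted p = 7.22e-10). Tex11 (chrX:100838648–100838897), needed for meiotic recombination, rose from 9.411 ± 3.4 to 80.93 ± 4.83 CPM (log2 3.07 ± 0.32, adjusted p = 8.22e-20). Mael and Tdrkh (chr3:94425965–94426214), genes of the piRNA pathway, rose by log2 3.14 ± 0.58 and at least 6.65-fold from 0 counts. The piRNA helicase Mov10l1 rose 39.9-fold (10.8 to 333) and the meiotic histone reader Zcwpw1 (chr5:137822360–137822621) by 1.81 ± 0.20. Naive pluripotency genes fell (0 and 12 of 19, 1 and 12 adjusted over the list alone, adjusted p = 4.85e-09). Klf4 (chr4:55527137–55527520), a reprogramming factor, changed by −1.81 ± 0.17 (38.8% multimapping reads, so uncertain). Its relative Klf2 changed by −1.08 ± 0.10, the kinase co-activator Tcl1 by −1.29 ± 0.11 and the threonine dehydrogenase Tdh by −1.14 ± 0.10. Nanog, the naive homeobox factor, stood at 529.3 ± 19.2 CPM in wild-type and 310.3 ± 38.3 CPM in Rybp-null cells.

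In the same Rybp-null cells the forebrain regulators Otx2 (49.1 ± 6.38 to 2.727 ± 0.932 CPM, log2 −4.09 ± 0.46, adjusted p = 4.01e-20) and Zic2 (chr14:122479998–122480328, 98.43 ± 14 to 8.885 ± 3.11 CPM, log2 −3.47 ± 0.26) fell. So did the eye regulator Vax2 (chr6:83738052–83738307) by 79.7-fold (26.8 to 391) and the oncofetal RNA-binding gene Igf2bp3 (chr6:49085218–49085477) by log2 −6.24 ± 0.83. Cdkn2a (chr4:89274473–89274722), the senescence-linked cell cycle inhibitor, fell from 76.91 ± 7.94 to 11.32 ± 2.19 CPM (log2 −2.72 ± 0.31, adjusted p = 3.1e-15). Cell cycle inhibitors had 1 higher and 3 lower of 5 (1 and 3 adjusted over the list alone, adjusted p = 0.0328). The p53 targets fell (1 and 9 of 19, 1 and 12 adjusted over the list alone, adjusted p = 7.16e-05). They included the pro-apoptotic Perp (−1.93 ± 0.30) and Pmaip1 (−1.48 ± 0.16). Variant PRC1 genes had 0 higher and 5 lower of 17 (0 and 5 adjusted over the list alone, adjusted p = 0.00128). They included L3mbtl2 (−0.59) besides the deleted Rybp, which fell 598-fold (107 to 23694). Without Rybp 4 of the other 16 fell (4 adjusted over the list alone) and the list call ended (adjusted p = 0.212). Imprinted genes had 7 higher and 2 lower of 20 (7 and 2 adjusted over the list alone, adjusted p = 0.00285). The placental growth repressor Phlda2 stood at 2.80 ± 0.26 and Dlk1, a maternally silenced Notch ligand, at 2.12 ± 0.40. The de novo methyltransferase Dnmt3b rose by 1.32 ± 0.12.

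Hox genes had 0 calls of 20 (0 adjusted over the list alone, adjusted p = 0.837). Core pluripotency (1 and 5 of 12), formative (4 and 3 of 11), primitive endoderm (3 and 1 of 16), neural (2 and 4 of 18), trophectoderm (3 and 4 of 15), PRC2 (1 and 2 of 12), canonical PRC1 (1 and 4 of 11), 2-cell-like (1 and 0 of 14) and ribosomal protein genes (3 and 12 of 41) moved without a list test below 0.05. Adjusted over the list alone these were 1 and 5, 4 and 3, 3 and 1, 3 and 5, 4 and 5, 1 and 2, 2 and 4, 1 and 0, and 4 and 13. Altogether 1192 genes were higher and 1392 lower (398 and 588 by at least 2-fold). Of 400 X-linked genes 241 were lower and 8 higher, and of 345 on chromosome 14 139 were lower and 12 higher. Among genes averaging at least 20 CPM the median was log2 −0.90 for 228 X-linked genes and −0.47 for 188 on chromosome 14. Zic2, Otx2 and Tdh lie on chromosome 14, so part of their falls may come from the shift of that chromosome. The list tests were not repeated without these chromosomes.

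Ring1-null cells, which keep Rnf2, were compared with wild-type cells at 0 h (3 against 3) to ask how this line differed. The testis-expressed gene Tex13b (chrX:140808307–140808616) fell from 68.89 ± 8.64 to 5.044 ± 0.153 CPM (log2 −3.76 ± 0.42, adjusted p = 1.42e-18). The G1 cyclin Ccnd2 (chr6:127125164–127125415) fell from 106.6 ± 11.1 to 28.21 ± 2.62 CPM (−1.93 ± 0.19). Vax2 changed by −2.42 ± 0.33, Cdkn2a by −1.07 ± 0.24, the trophoblast factor Ets2 by −0.86 ± 0.13 and the PRC2 subunit Eed by −0.53 ± 0.12 (adjusted p = 0.00142). The metalloprotease gene Amz1 (chr5:140753063–140753312) and the neuronal Crmp1 rose by 1.70 ± 0.37 and 1.46 ± 0.31. The neural regulator Sox3 rose by 0.97 ± 0.23, a call that ended without wild-type 0 h replicate 3 (0.88, adjusted p = 0.0648). In the Rnf2-degron clones at 0 h, which also lack Ring1, Tex13b (log2 4.41 ± 0.40), Cdkn2a (1.45 ± 0.21, adjusted p = 5.04e-09) and Vax2 (1.32 ± 0.32, adjusted p = 0.000712) stood higher than in the Ring1-null line. Amz1 (−1.59, adjusted p = 2.44e-06) and Crmp1 (−0.75, adjusted p = 0.0171) stood lower there, values not put through the alternatives. These differences from wild-type were thus not shared in full by every line lacking Ring1. Imprinted genes passed the list test (1 and 0 of 20, 4 and 0 adjusted over the list alone, adjusted p = 0.000805). Ribosomal protein genes did so with 0 calls of 41 (adjusted p = 0.0132 and adjusted p = 0.489 with an estimated correlation). Formative genes had 2 higher and 0 lower of 11 (2 and 0 adjusted over the list alone, adjusted p = 0.148). Hox genes had 0 calls of 20 (adjusted p = 0.558). Altogether 62 genes were higher and 58 lower (13 and 10 by at least 2-fold), and 79 genes were called when chromosomes 6, 8, 14 and X were left out.

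Auxin alone was tested at 48 h against 0 h in each line without a degron (3 against 3). No gene was called by edgeR or DESeq2 in wild-type, Eed-null or Ring1-null cells. At unadjusted p < 0.05 edgeR gave 654, 608 and 749 genes, and 24, 50 and 17 were called when each line was fitted alone. Ribosomal protein genes, the translation machinery, passed the list test with 0 calls in wild-type (adjusted p = 2.83e-14 and adjusted p = 0.0924 with an estimated correlation), Eed-null (7.82e-06 and adjusted p = 0.498 with an estimated correlation) and Ring1-null cells (4.31e-19). Primitive endoderm genes did so in Eed-null cells (adjusted p = 0.015) with 0 calls of 16 (1 and 0 adjusted over the list alone). In Rybp-null cells 57 genes were higher and 74 lower (25 and 3 by at least 2-fold). The lysosomal Manba (chr3:135571154–135571403) went from 22.2 ± 13 to 182.6 ± 24.9 CPM (log2 3.10 ± 0.77), a call that ended without Rybp-null 0 h replicate 2 (2.71, adjusted p = 0.0984). The imprinted receptor gene Igf2r rose from 32.65 ± 4.83 to 61.01 ± 11.2 CPM (0.86 ± 0.19, adjusted p = 0.00508). The 131 calls became 24, 82 or 81 without Rybp-null 0 h replicate 2, 0 h replicate 1 or 48 h replicate 1. They became 30, of which 76.7% were higher against 43.5%, when the line was fitted alone, 78 without that 48 h library and wild-type 48 h replicate 1, and 205 without the low-count filter.

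To follow loss of Rybp in cells already lacking Eed, the Rybp-degron clones were compared at 6, 24 and 48 h with 0 h (6 against 6, the mean of the effects of both clones). Lines without a degron were not sampled at 6 or 24 h. Changes at these times, here and in the other degron genotypes, therefore cannot be separated from effects of auxin or handling. At 6 h pluripotency genes had begun to fall. Foxd3 (chr4:99658422–99658672), a core pluripotency factor, changed by log2 −0.99 ± 0.11 (adjusted p = 4.67e-12) and Sox2 (chr3:34652203–34652463) by −0.52 ± 0.07. Core genes had 0 higher and 3 lower of 12 (0 and 5 adjusted over the list alone, adjusted p = 5.62e-11). Naive genes had 0 and 6 of 19 (0 and 10 adjusted over the list alone, adjusted p = 4.15e-12). The mesodermal regulators Tbx1 (chr16:18581704–18581953) and Foxf1 (chr8:121087905–121088154) rose by 2.98 ± 0.67 and 2.78 ± 0.65. Mesoderm (3 and 0 of 13, adjusted p = 6.94e-09), Hox (2 and 0 of 20, adjusted p = 1.11e-10), germline (2 and 0 of 28, adjusted p = 8.96e-09) and neural genes (4 and 0 of 18, adjusted p = 4.23e-05) shifted up. In that order 7 and 0, 10 and 0, 10 and 0, and 5 and 1 genes were called adjusted over the list alone. Altogether 60 genes were higher and 68 lower (30 and 0 by at least 2-fold). The share of higher calls, 46.9%, was 57% with RLE scaling. The 128 calls became 83 without C3 0 h replicate 3, 285 without A12 6 h replicate 2, 84 with DESeq2, 61 when fitted alone and 18 in clone C3 alone. Library A12 6 h replicate 3 stood apart from the others of its group (chi-square per degree of freedom 5.621 and 8, against 1.495 between those others), and 87 genes were called without it.

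At 24 h, 614 genes were higher and 624 lower (124 and 20 by at least 2-fold), 698 in A12 alone and 381 in C3 alone. Germline (16 and 0 of 28, 17 and 1 adjusted over the list alone, adjusted p = 1.25e-14) and trophectoderm genes (7 and 1 of 15, 8 and 1 adjusted over the list alone, adjusted p = 1.52e-09) rose. The homeobox gene Six2 rose by 2.65 ± 0.42 and Tex11 by 1.14 ± 0.10. Core genes had 0 higher and 9 lower of 12 (0 and 10 adjusted over the list alone, adjusted p = 2.24e-09).

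At 48 h in the Rybp-degron clones trophectoderm (12 and 1 of 15, 12 and 1 adjusted over the list alone, adjusted p = 2.64e-09) and germline genes rose (17 and 1 of 28, 19 and 2 adjusted over the list alone, adjusted p = 1.86e-10). Hand1 (chr11:57828713–57828962), a trophoblast and heart regulator, rose by log2 2.37 ± 0.42 (adjusted p = 5.3e-08), the signalling ligand Wnt7b (chr15:85535437–85535688) by 2.36 ± 0.21 (5.71e-21). The caudal homeobox gene Cdx1 rose by 1.98 ± 0.29, the epithelial keratin Krt8 by 1.35 ± 0.17 (68.9% multimapping reads, so uncertain), Mael by 1.79 ± 0.28 and Tex11 by 1.08 ± 0.11. The stem cell antigen Ly6a (chr15:74994877–74995127) rose by 2.39 ± 0.28 (7.9e-15). Mesoderm (9 and 0 of 13, 9 and 0 adjusted over the list alone, adjusted p = 6.25e-06), primitive endoderm (6 and 0 of 16, 6 and 0 adjusted over the list alone, adjusted p = 7.83e-08) genes also rose. So did Hox (7 and 0 of 20, 8 and 0 adjusted over the list alone, adjusted p = 0.00484) and imprinted genes (10 and 3 of 20, 11 and 4 adjusted over the list alone, adjusted p = 0.000908). Among them were Hoxb7 (chr11:96289914–96290163) at 1.70 ± 0.37, the X-linked homeobox gene Rhox5 at 1.32 ± 0.08 and H19 (chr7:142575530–142575779) at 1.84 ± 0.33.

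Pluripotency genes fell at 48 h in the same Rybp-degron clones. Core genes had 0 higher and 8 lower of 12 (0 and 8 adjusted over the list alone, adjusted p = 1.21e-08). Naive genes had 3 and 9 of 19 (3 and 10 adjusted over the list alone, adjusted p = 0.00147) and formative genes 2 and 6 of 11 (2 and 6 adjusted over the list alone, adjusted p = 0.00148). The Nodal co-receptor Tdgf1 changed by −0.89 ± 0.08, Sox2 by −0.74 ± 0.07, the RNA-binding Lin28a by −0.74 and the orphan receptor Nr0b1 by −0.94. Zic2 changed by −1.63 ± 0.11, from 114.7 ± 8.27 (A12) and 166.8 ± 16.8 (C3) to 50.37 ± 4.27 and 40 ± 7.8 CPM. The muscle actinin Actn3 (chr19:4861216–4861472) fell as well (−2.60 ± 0.39, adjusted p = 3.85e-11). Ribosomal protein genes had 0 higher and 7 lower of 41 (0 and 7 adjusted over the list alone, adjusted p = 0.00157 and adjusted p = 0.321 with an estimated correlation). Of these, Rpl15 and Rpl5 had 97.1 and 98.7% multimapping reads and turned direction without them. Turns of this kind in other contrasts are given below. Neural (5 and 3 of 18) and p53 genes (2 and 4 of 19) passed no test (6 and 4, and 3 and 5, adjusted over the list alone), and cell cycle inhibitors and 2-cell-like genes had 0 calls. Altogether 999 genes were higher and 999 lower (248 and 120 by at least 2-fold), and 842 were called in A12 alone and 1314 in C3 alone.

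**Figure D2:**
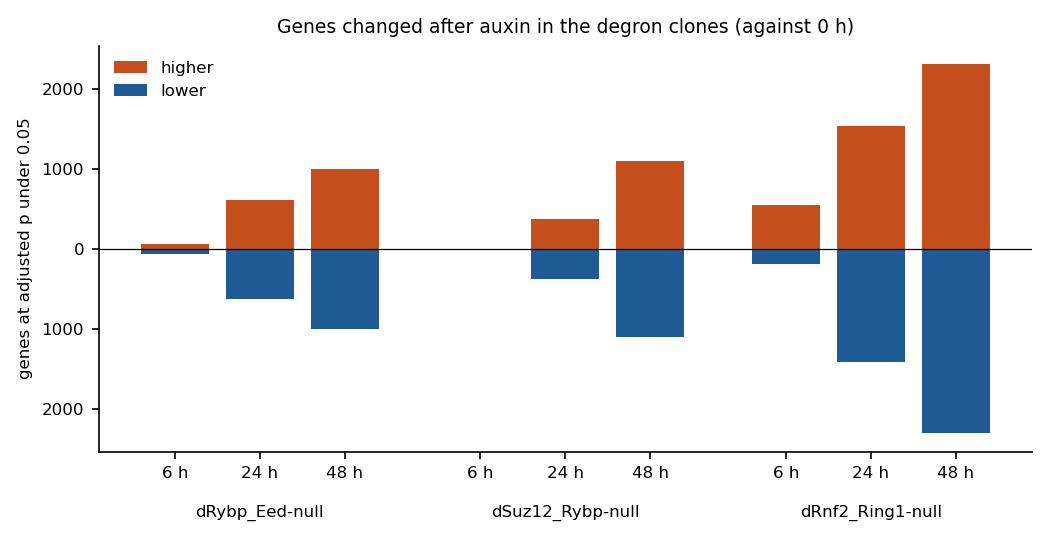
Genes higher (up) and lower (down) than 0 h at edgeR adjusted p < 0.05 after 6, 24 and 48 h of auxin in each degron genotype, 6 libraries per time over 2 clones.

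Loss of Suz12 in cells already lacking Rybp was followed in the Suz12-degron clones (6 against 6). At 6 h 4 genes rose and 0 fell. The fourth, Ccnd2 (log2 1.01), a G1 cyclin gene, falls outside the naming rule, was added after the values were seen and was not put through the alternatives. The neural repressor Sox21 and the homeobox gene Msx1 (chr5:37820491–37820740) rose 13.3-fold each (4.21 to 67 and 3.32 to 115) and Sox3 (chrX:60891366–60891619), an early neural factor, by 0.92 ± 0.14 (adjusted p = 2.22e-06). In A8 alone Sox21 (3.66, adjusted p = 0.0685) and Msx1 (2.29, 0.346) were not called, Msx1 was not called by DESeq2 (3.62, 0.0763), and Sox3 was not called in B11 alone (0.64, 0.343). Formative (1 and 0 of 11, 1 and 0 adjusted over the list alone, adjusted p = 1.12e-06), mesoderm (1 and 0 of 13, 2 and 0 adjusted over the list alone, adjusted p = 2.16e-05) and neural genes (0 of 18, 1 and 0 adjusted over the list alone, adjusted p = 0.00168) shifted up. DESeq2 called 2 genes, and 1, 1, 2 and 1 were called with these libraries fitted alone, in A8, in B11 and without chromosomes 6, 8, 14 and X.

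At 24 h in these Suz12-degron clones 374 genes were higher and 375 lower (109 and 8 by at least 2-fold). The endoderm regulator Gata6 (chr18:11085386–11085635) rose by 3.05 ± 0.45 (adjusted p = 6.72e-12), the PRC1 gene Bmi1 (chr2:18686380–18686629) by 2.81 ± 0.48, Cdkn2a by 2.32 ± 0.35 and Zic2 by 1.39 ± 0.20. Primitive endoderm (5 and 0 of 16, 15 and 0 adjusted over the list alone, adjusted p = 1.24e-11), Hox (6 and 0 of 20, 13 and 0 adjusted over the list alone, adjusted p = 2.12e-06) and germline genes (7 and 0 of 28, 12 and 0 adjusted over the list alone, adjusted p = 6.27e-10) rose. Core genes fell (0 and 3 of 12, 0 and 3 adjusted over the list alone, adjusted p = 4.86e-05). The PRC2 list had a median of −0.13, a mean of 0.04 and a test pointing down (adjusted p = 0.0334 and adjusted p = 0.0558 with an estimated correlation). Fitted alone these libraries gave 471 calls, A8 alone 346 and B11 alone 196.

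By 48 h nearly every tested Hox and primitive endoderm gene had risen in the Suz12-degron clones. Hox genes had 19 higher and 0 lower of 20 (20 and 0 adjusted over the list alone, adjusted p = 1.16e-16). Hoxb7 rose 75.5-fold (13.2 to 3.01e+03), Hoxa11 53.7-fold (9.29 to 2.15e+03), Hoxa10 34.4-fold (9.22 to 289) and Hoxa7 (chr6:52215624–52215873) at least 21.5-fold from 0 counts. All 16 primitive endoderm genes rose (16 and 0 adjusted over the list alone, adjusted p = 8.58e-40). Gata6 went from 1.202 ± 1.04 (A8) and 2.293 ± 0.643 (B11) to 28.67 ± 4.68 and 39.18 ± 2 CPM (log2 4.30 ± 0.44, adjusted p = 7.62e-27). Gata4 rose 33-fold (11 to 162), the forkhead gene Foxq1 by 4.14 ± 0.48 and Col4a1 by 1.81 ± 0.13. Trophectoderm (10 and 0 of 15, 11 and 0 adjusted over the list alone, adjusted p = 2.41e-09) and germline (14 and 0 of 28, 18 and 0 adjusted over the list alone, adjusted p = 7.98e-09) genes rose too. So did mesoderm (7 and 0 of 13, 8 and 0 adjusted over the list alone, adjusted p = 8.57e-06) and neural genes (9 and 2 of 18, 10 and 2 adjusted over the list alone, adjusted p = 0.000805). They included Elf3 (1.40 ± 0.11), Tfap2c (1.74 ± 0.19), the meiotic entry gene Stra8 (chr6:34939093–34939344, 1.06 ± 0.14), the germ cell translation factor Dazl (1.09 ± 0.18), the streak regulator Evx1 (3.47 ± 0.52) and Tbx5, 25.4-fold (8.43 to 126).

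In these Suz12-degron clones Cdkn2a went from 3.336 ± 2.99 (A8) and 4.764 ± 1.8 (B11) to 58.78 ± 3.65 and 54.72 ± 1.21 CPM (log2 3.72 ± 0.33, adjusted p = 7.76e-26). Zic2 went from 8.769 ± 2.71 and 12.24 ± 1.29 to 44.18 ± 2.53 and 52.24 ± 7.53 CPM (2.25 ± 0.19). Cdkn2a and Zic2 stayed below their wild-type levels given above. Otx2 rose by 1.68 ± 0.25 and the PRC1 genes Bmi1 and Cbx8 by 3.84 ± 0.46 and 3.10 ± 0.48. Cell cycle inhibitors had 4 higher and 0 lower of 5 (4 and 0 adjusted over the list alone, adjusted p = 1.67e-06). The p53 targets had 5 and 0 of 19 (5 and 0 adjusted over the list alone, adjusted p = 0.00638), with Pmaip1 at 1.44 ± 0.11. Core pluripotency genes fell (0 and 9 of 12, 0 and 10 adjusted over the list alone, adjusted p = 2.42e-06). Pou5f1, the master pluripotency factor, changed by −0.33 ± 0.05 (98.4% multimapping reads, so uncertain) and the chromatin factor Dppa4 by −0.58 ± 0.06. The PRC1 gene Phc1 (chr6:122318294–122318547) fell by 0.91 ± 0.06 and the nucleoside transporter Slc28a1 by 1.95 ± 0.22. Naive (5 and 4 of 19) and imprinted genes (8 and 3 of 20) passed no test (6 and 4, and 8 and 4, adjusted over the list alone), and 2-cell-like genes had 0 calls. Altogether 1101 genes were higher and 1099 lower (339 and 71 by at least 2-fold), and 1107 were called in A8 alone and 1159 in B11 alone.

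Loss of Rnf2 in cells already lacking Ring1 was followed in the Rnf2-degron clones (6 against 6). At 6 h Hox genes had already risen (19 and 0 of 20, 20 and 0 adjusted over the list alone, adjusted p = 1.36e-59). Hoxa11 rose 111-fold (19.6 to 4.42e+03), Hoxb7 51.9-fold (14 to 434), Hoxa9 38.6-fold (12.9 to 189) and Hoxb2 at least 13.8-fold from 0 counts. Germline (20 and 0 of 28, 22 and 0 adjusted over the list alone, adjusted p = 6.44e-26) and neural (15 and 0 of 18, 16 and 0 adjusted over the list alone, adjusted p = 6.6e-27) genes rose. So did mesoderm (7 and 0 of 13, 10 and 0 adjusted over the list alone, adjusted p = 4.81e-21) and primitive endoderm genes (7 and 0 of 16, 8 and 0 adjusted over the list alone, adjusted p = 3.78e-09). Sox3 rose by log2 1.96 ± 0.12 (adjusted p = 2.63e-29), Msx1 by 3.21 ± 0.33, Evx1 by 2.28 ± 0.23 and Tex101 (chr7:24668010–24668262), a germ cell antigen gene, by 2.12 ± 0.23. Tbx1 rose 83.5-fold (14.6 to 3.34e+03) and Igf2 (chr7:142650768–142651018), the paternally expressed growth factor, 59.7-fold (10.3 to 2.39e+03). Foxd3 fell by 0.87 ± 0.11 and Nanog by 0.51 ± 0.06. Naive genes had 0 higher and 6 lower of 19 (0 and 11 adjusted over the list alone, adjusted p = 9.5e-10) and core genes 0 and 4 of 12 (1 and 6 adjusted over the list alone, adjusted p = 2.44e-07). No 2-cell-like gene was called. Altogether 549 genes were higher and 188 lower (291 and 1 by at least 2-fold), 74.5% higher against 85.5% with DESeq2. In single clones 431 genes were called in B10 alone and 320 in C2 alone.

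At 24 h in the Rnf2-degron clones 1531 genes were higher and 1418 lower (682 and 107 by at least 2-fold), 51.9% higher against 62.9% with DESeq2, and 1696 genes were called in C2 alone. All 20 Hox genes were higher (20 and 0 adjusted over the list alone, adjusted p = 2.35e-26) and 11 of 12 core genes lower (0 and 11 adjusted over the list alone, adjusted p = 1.21e-07). Of 14 2-cell-like genes, which mark totipotent-like cells, 13 were higher (13 and 0 adjusted over the list alone, adjusted p = 1.05e-27). Gm20767 (chr13:120155086–120155335) rose by 4.32 ± 0.26, while Gm4340 rested on multimapping reads alone. Ribosomal protein genes had 0 higher and 20 lower of 41 (0 and 27 adjusted over the list alone, adjusted p = 2.13e-05 and adjusted p = 0.169 with an estimated correlation).

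At 48 h all 20 Hox genes were higher in the Rnf2-degron clones (20 and 0 adjusted over the list alone, adjusted p = 1.48e-16). Hoxa11 rose 279-fold (49.8 to 11046) and Hoxb7 82.1-fold (22.5 to 682). Germline (23 and 1 of 28, 23 and 1 adjusted over the list alone, adjusted p = 1.88e-10) and trophectoderm (12 and 1 of 15, 13 and 1 adjusted over the list alone, adjusted p = 7.26e-08) genes rose. So did mesoderm (12 and 0 of 13, 12 and 0 adjusted over the list alone, adjusted p = 2.13e-05) and primitive endoderm (14 and 1 of 16, 14 and 1 adjusted over the list alone, adjusted p = 1.51e-13) genes. Neural (12 and 2 of 18, 13 and 2 adjusted over the list alone, adjusted p = 0.0187), imprinted (11 and 5 of 20, 11 and 5 adjusted over the list alone, adjusted p = 4.2e-07) and 2-cell-like genes (13 and 0 of 14, 13 and 0 adjusted over the list alone, adjusted p = 0.00171) rose. Gata6 went from 0.8647 ± 0.813 (B10) and 1.867 ± 1.46 (C2) to 28.1 ± 5.09 and 33.3 ± 3.24 CPM (log2 4.55 ± 0.52, adjusted p = 4.2e-28). Wnt7b rose by 4.39 ± 0.54, Tex101 by 3.37 ± 0.22, Tex11 by 2.18 ± 0.13, Gm20767 by 4.54 ± 0.26, the oocyte gene Dppa3 by 2.93 ± 0.15 and Igf2 171-fold (30.5 to 6.8e+03). H19 went from 9.402 ± 0.492 (B10) and 12.7 ± 2.08 (C2) to 151.9 ± 1.76 and 325.1 ± 14.7 CPM (4.35 ± 0.19). Fbxo15 (chr18:84981143–84981472) went from 323 ± 32.2 and 331.3 ± 25.7 to 2019 ± 77.2 and 883.2 ± 74.2 CPM (2.03 ± 0.06).

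In the same Rnf2-degron clones at 48 h core pluripotency genes fell (0 and 11 of 12, 0 and 11 adjusted over the list alone, adjusted p = 7.77e-10). Tdgf1 fell by 1.21 ± 0.08 (adjusted p = 8.05e-27). Sox2 fell by 0.88 ± 0.07. Pou5f1 went from 3080 ± 194 (B10) and 3156 ± 108 CPM (C2) at 0 h to 2196 ± 68.4 and 2262 ± 235 CPM at 48 h, uncertain levels because 98.4% of its reads were multimapping. Trh (chr6:92242060–92242310), the thyrotropin-releasing hormone gene, went from 936.3 ± 151 and 911.6 ± 47.8 to 41.46 ± 5.4 and 74.52 ± 5.4 CPM (−4.06 ± 0.11, adjusted p = 3.29e-63). The arginine transporter Slc7a3 (chrX:101079209–101079459) fell by 2.77 ± 0.07. Phc1 (−1.31 ± 0.06), Eed (−0.84 ± 0.09), the neuronal tubulin Tubb3 (−1.91 ± 0.10) and the mesenchymal filament Vim (−1.71 ± 0.12) fell as well. Cell cycle inhibitors had 4 higher and 0 lower of 5 (4 and 0 adjusted over the list alone, adjusted p = 0.0378). Cdkn2a stood at 176.6 ± 17.6 and 192.3 ± 29.8 CPM (0.90 ± 0.11). Ribosomal protein genes had 0 higher and 26 lower of 41 (0 and 31 adjusted over the list alone, adjusted p = 0.00102 and adjusted p = 0.299 with an estimated correlation). Naive (5 and 10 of 19) and p53 genes (9 and 3 of 19) passed no test (5 and 10, and 9 and 5, adjusted over the list alone). Altogether 2311 genes were higher and 2302 lower (911 and 289 by at least 2-fold), 50.1% higher against 60.5% with DESeq2, and 2921 were called in B10 alone.

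**Figure D3:**
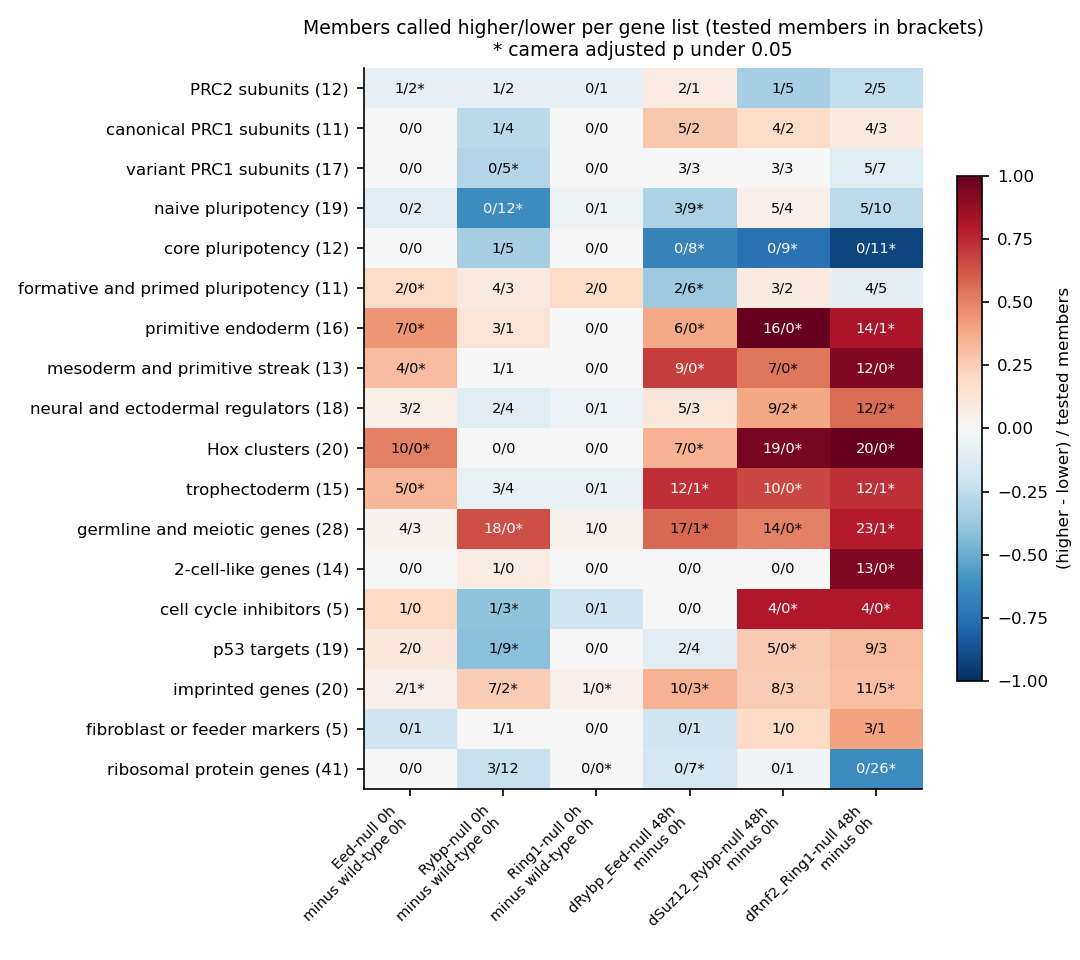
Gene lists in each null line against wild-type and each degron genotype at 48 h against 0 h. Text gives tested genes higher/lower, colour their difference over the number tested, and * marks camera adjusted p < 0.05 with deleted genes included.

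To separate loss of the tagged protein from auxin, the 48 h effect in each degron genotype was compared with the 48 h effect in its parental null line (12 against 6). In the Rybp-degron clones Wnt7b rose by log2 2.50 ± 0.53 and Rhox5 by 1.35 ± 0.17 beyond auxin. Zic2 (−1.69 ± 0.16, adjusted p = 1.88e-15), Tdgf1 (−0.88 ± 0.14) and Actn3 (−2.55 ± 0.45) fell. Core (0 and 4 of 12, 0 and 5 adjusted over the list alone, adjusted p = 8.37e-05) and formative (2 and 5 of 11, 2 and 5 adjusted over the list alone, adjusted p = 0.00398) genes fell. The trophectoderm (4 and 1 of 15, 7 and 1 adjusted over the list alone, adjusted p = 0.000934) and germline lists (3 and 0 of 28, 6 and 0 adjusted over the list alone, adjusted p = 0.000326) rose. In the Suz12-degron clones Cdkn2a (3.77 ± 0.52, adjusted p = 1.07e-08), Gata6 (3.71 ± 0.69) and Zic2 (2.85 ± 0.44) rose and Nr0b1 fell (−1.36 ± 0.19). Primitive endoderm (9 and 0 of 16, 15 and 0 adjusted over the list alone, adjusted p = 4e-15) and cell cycle inhibitor genes rose (2 and 0 of 5, 3 and 0 adjusted over the list alone, adjusted p = 8.37e-05), as did germline genes (4 and 0 of 28, 7 and 0 adjusted over the list alone, adjusted p = 7.52e-05). In the Rnf2-degron clones Trh (−4.01 ± 0.17, adjusted p = 8.94e-44), Tdgf1 (−1.17 ± 0.13) and Phc1 (−1.37 ± 0.10) fell. H19 (4.48 ± 0.32), Dppa3 (3.58 ± 0.34), Tex101 (3.81 ± 0.42) and Fbxo15 (1.94 ± 0.12) rose. Core genes fell (0 and 9 of 12, 0 and 9 adjusted over the list alone, adjusted p = 0.000326). Primitive endoderm (10 and 0 of 16, 12 and 1 adjusted over the list alone, adjusted p = 0.00398) and germline genes rose (10 and 0 of 28, 11 and 0 adjusted over the list alone, adjusted p = 0.0321), as did imprinted genes (11 and 2 of 20, 11 and 3 adjusted over the list alone, adjusted p = 0.0321). Hox lists passed no test (0, 1 and 7 higher of 20, adjusted p = 0.0647, 0.0612 and 0.101, with 0, 6 and 12 adjusted over the list alone). Some Hox genes were near absence before auxin. Hoxa7 had 0 counts in the Suz12-degron clones at 0 h, and Hoxa11 and Hoxb2 had 1 and 0 in the Rnf2-degron clones. A difference of effects is poorly measured at such counts, so the missing list calls do not show that auxin raised these genes. The 2-cell-like calls in the Rnf2-degron clones, 4 higher of 14 (4 and 0 adjusted over the list alone), differed in sign from their list test. The PRC2 list in the Suz12-degron clones had a median of −0.27, a mean of 0.05 and a test pointing down (adjusted p = 0.0118).

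Beyond auxin 248 genes were higher and 254 lower in the Rybp-degron clones (104 and 79 by at least 2-fold), 337 and 365 in the Suz12-degron clones (145 and 83), and 797 and 1041 in the Rnf2-degron clones (501 and 285, 43.4% higher against 54% with DESeq2). The 502 calls of the Rybp-degron clones became 765 when fitted alone and 211 in A12 alone. The 702 calls of the Suz12-degron clones became 451 without Rybp-null 0 h replicate 2 and 418 in B11 alone.

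The 48 h responses of the 3 degron genotypes were compared for shared genes. The PRC1 gene Phc1 fell by log2 0.54 with Rybp, 0.91 with Suz12 and 1.31 with Rnf2 depletion, and Nr0b1 by 0.94, 1.07 and 2.01. Cdx1 rose by 1.98, 1.52 and 3.84. Both Rybp and Rnf2 depletion gave 772 higher and 760 lower genes, against 224.9 and 224 for independent calls, and 34 genes moved in opposite directions. Rybp and Suz12 depletion shared 329 and 310 (107.2 and 107) with 127 opposite, and Suz12 and Rnf2 depletion 662 and 603 (247.9 and 246.5) with 162 opposite. At 2-fold or more the pairs shared 214 and 73, 74 and 12, and 209 and 24. All 3 genotypes shared 300 higher and 280 lower genes. Across genes, which are not independent replicates, Pearson r was 0.58, 0.301 and 0.517 and Spearman rho 0.574, 0.247 and 0.397 in the same order.

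Direct differences between the 48 h effects were tested for each pair (12 against 12). Hox genes rose less with Rybp depletion in Eed-null cells than with Suz12 depletion in Rybp-null cells (0 and 17 of 20, 0 and 18 adjusted over the list alone, adjusted p = 1.21e-11). So did primitive endoderm genes (1 and 12 of 16, 1 and 13 adjusted over the list alone, adjusted p = 2.76e-14). The Rybp-degron clones started from raised Hox levels. At 0 h Hoxa10 and Hoxa11 stood log2 1.22 and 1.58 above the Eed-null line, itself 57.9-fold and 34.4-fold above wild-type. In the Suz12-degron clones at 0 h these genes had 2 and 1 counts. A smaller rise therefore does not mean a lower level at 48 h. Gata6 differed by log2 −3.94 ± 0.50 (adjusted p = 1.97e-13), Cdkn2a by −3.48 ± 0.36 (2.64e-19) and Col4a1 by −1.34 ± 0.15. Neural (1 and 7 of 18, 2 and 7 adjusted over the list alone, adjusted p = 0.000583) and p53 genes were lower in this difference (0 and 4 of 19, 0 and 4 adjusted over the list alone, adjusted p = 0.001), as were cell cycle inhibitors (0 and 3 of 5, 1 and 4 adjusted over the list alone, adjusted p = 6.27e-06). Against Rnf2 depletion, Rybp depletion raised Hox genes less (0 and 18 of 20, 0 and 20 adjusted over the list alone, adjusted p = 1.32e-09). The same held for primitive endoderm (0 and 12 of 16, 1 and 12 adjusted over the list alone, adjusted p = 4e-05) and trophectoderm genes (0 and 8 of 15, 0 and 10 adjusted over the list alone, adjusted p = 0.037). Gata6 differed by −4.19 ± 0.57 and Hoxa7 by −3.71 ± 0.58. Foxd3 was higher in this difference (1.28 ± 0.15), among core genes with 4 higher and 0 lower of 12 (8 and 0 adjusted over the list alone, adjusted p = 0.0481).

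Suz12 and Rnf2 depletion did not differ by list test for Hox genes (1 and 0 of 20, 0 adjusted over the list alone, adjusted p = 0.891). Germline (3 and 13 of 28, 5 and 17 adjusted over the list alone, adjusted p = 0.0202) and imprinted genes (3 and 10 of 20, 4 and 11 adjusted over the list alone, adjusted p = 0.037) were lower after Suz12 than after Rnf2 depletion in this difference of effects. Core genes fell less (7 and 1 of 12, 8 and 1 adjusted over the list alone, adjusted p = 0.0202). Of 14 2-cell-like genes, 6 were lower in this difference (7 adjusted over the list alone), with Gm20767 at −4.44 ± 0.61. Tex11 differed by −1.74 ± 0.17, Tex101 by −2.46 ± 0.31, Tdgf1 by 1.25 ± 0.12 (adjusted p = 4.66e-17), Tubb3 by 1.98 ± 0.15 and Cdkn2a by 2.82 ± 0.35 (1.39e-14). Cdkn2a rose more after Suz12 depletion but from a far lower start. Its level at 48 h, as given above, stayed below that in the Rnf2-degron clones. In the order given, 558 genes were higher and 678 lower, 468 and 684, and 1126 and 1103.

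The sum of the separate effects of Eed and Rybp loss was compared with the effect of a combined loss, using each degron genotype at 48 h. The Rybp-degron clones lack Eed and had Rybp targeted for 48 h. The Suz12-degron clones lack Rybp, had Suz12 targeted for 48 h and still make Eed RNA, so there Suz12 loss is set against Eed loss. Loss of the tagged proteins was not measured here. The subtracted null lines lack their gene throughout. A departure from the sum therefore cannot be told apart from effects of duration of loss or differences between lines. In the Rybp-degron clones these genes stood above the sum: Igf2bp3 by log2 5.27 ± 0.77 (adjusted p = 2.8e-17), Cdkn2a by 2.45 ± 0.36, Otx2 by 2.04 ± 0.41, Zic2 by 1.96 ± 0.36 and Tdh by 1.30 ± 0.14. Naive (8 and 1 of 19, 8 and 3 adjusted over the list alone, adjusted p = 0.0101) and cell cycle inhibitor genes (2 and 0 of 5, 2 and 0 adjusted over the list alone, adjusted p = 0.0342) lay above it. Stra8 (−3.27 ± 0.37), Phlda2 (−2.48 ± 0.29), Phc1 (−1.46 ± 0.11) and Zcwpw1 (−1.23) lay below it. Stra8 was already lower in these clones than in Eed-null cells before auxin. Igf2bp3, Cdkn2a, Otx2, Zic2 and Tdh were each lower in Rybp-null than in wild-type cells at 0 h. The germline list passed no test (1 and 7 of 28, 1 and 7 adjusted over the list alone, adjusted p = 0.0678). Ribosomal protein genes had 0 higher and 9 lower of 41 (0 and 9 adjusted over the list alone, adjusted p = 0.0101 and adjusted p = 0.491 with an estimated correlation). In the Suz12-degron clones Bmi1 (3.31), Zic2 (2.08 ± 0.35), Cdkn2a (1.46 ± 0.37) and Tcl1 (0.82) lay above the sum and Cited1 (−2.49), Tex11 (−1.71 ± 0.40) and the imprinted zinc finger gene Peg3 (−1.54 ± 0.25) below it. The p53 (3 and 0 of 19, 6 and 0 adjusted over the list alone, adjusted p = 0.00467) and cell cycle inhibitor genes (2 and 0 of 5, 3 and 0 adjusted over the list alone, adjusted p = 0.00599) lay above it. So did naive genes (6 and 1 of 19, 6 and 1 adjusted over the list alone, adjusted p = 0.011), and Hox genes had 0 calls of 20 (adjusted p = 0.692).

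Against the sum of the single losses, 879 genes were higher and 777 lower in the Rybp-degron clones (483 and 326 by at least 2-fold), and 221 and 251 in the Suz12-degron clones (118 and 90). The rises of Rybp in the former and of Eed in the latter arise by construction, because the subtracted null line lacks that RNA and the degron line makes it. In the former 186 X-linked genes were higher and 7 lower, and 103 and 17 on chromosome 14, where Zic2, Otx2 and Tdh lie. The 472 calls of the latter became 271 and 314 without wild-type 48 h replicate 3 and replicate 2.

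**Figure D4:**
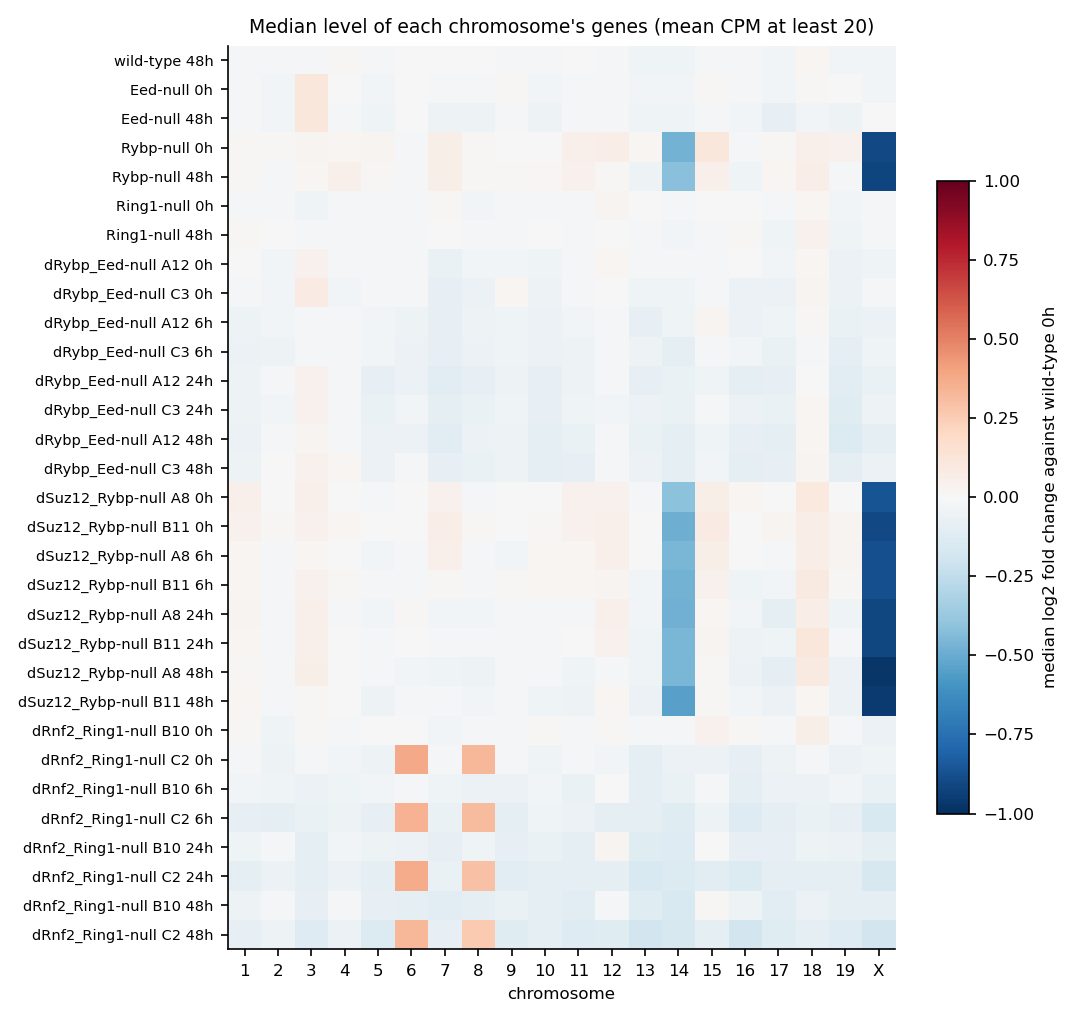
Median log2 fold change against wild-type 0 h of genes averaging at least 20 CPM, per chromosome and group (3 libraries each), coloured from −1 to 1.

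Degron clones were compared with their parental null line at 0 h (6 against 3) to see what differed before auxin. In the Rybp-degron clones the X-linked gene Xlr4b (chrX:73222201–73222453) stood 20-fold higher (6.68 to 98). Hoxa11 (log2 1.58 ± 0.26), Hoxa10 (1.22 ± 0.21), Tex11 (1.36 ± 0.20) and Rhox5 (0.83 ± 0.12) were higher, and Stra8 was lower (−1.94 ± 0.24, adjusted p = 1.29e-10). Rybp itself was lower by 1.79 ± 0.14 on average, with A12 at 0.14, so the fall came from C3. Primitive endoderm (6 and 0 of 16, 6 and 1 adjusted over the list alone, adjusted p = 3.82e-05) and Hox lists were higher (3 and 0 of 20, 6 and 0 adjusted over the list alone, adjusted p = 0.000183). Core genes were lower (0 and 2 of 12, 0 and 4 adjusted over the list alone, adjusted p = 0.00226). In the Suz12-degron clones Zcwpw1 was lower (−1.02 ± 0.13, adjusted p = 4.56e-09) with other germline genes (0 and 4 of 28, 0 and 10 adjusted over the list alone, adjusted p = 4.33e-08). Naive genes were higher (3 and 0 of 19, 5 and 2 adjusted over the list alone, adjusted p = 0.00952). In the Rnf2-degron clones Tex13b was higher (4.41 ± 0.40, adjusted p = 1.56e-29, 76.89 ± 5.76 CPM in B10 and 155.6 ± 12.1 in C2), as were Rnf2 (0.49 ± 0.09) and Tex11 (1.54). The lysine catabolism gene Aass (chr6:23072449–23072750, −3.16 ± 0.27) and Eed (−0.76 ± 0.11, adjusted p = 1.11e-08) were lower. Formative genes were lower (0 and 4 of 11, 0 and 7 adjusted over the list alone, adjusted p = 3.86e-05) and germline genes higher (4 and 0 of 28, 7 and 2 adjusted over the list alone, adjusted p = 0.0387).

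Before auxin 146 genes were higher and 331 lower in the Rybp-degron clones (34 and 53 by at least 2-fold), 125 and 172 in the Suz12-degron clones (35 and 34) and 240 and 309 in the Rnf2-degron clones (58 and 71). The first 477 became 278 and 302 without Eed-null 0 h replicate 2 and replicate 1, and 725 when fitted alone. The 297 became 82 and 154 without Rybp-null 0 h replicate 2 and replicate 1, 463 in A8 alone and 92 in B11 alone. The 549 became 321 and 328 without Ring1-null 0 h replicate 3 and replicate 2, 278 in B10 alone, 1004 in C2 alone and 359 without chromosomes 6, 8, 14 and X.

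Finally the 48 h effects of the clones of each genotype were compared (6 against 6). The stress gene Ddit4 fell less in A12, from 613 ± 53 to 368.9 ± 11.6 CPM, than in C3, from 691.5 ± 64.4 to 177.8 ± 93.2 CPM (log2 1.28 ± 0.19, adjusted p = 5.6e-07). Rhox5 rose less in A12 (−0.72). H19 stood at 2.127 ± 0.672 CPM in A12 and 180.5 ± 9.39 CPM in C3 at 0 h, and at 7.035 ± 4.1 and 665.1 ± 33.6 CPM at 48 h. Fbxo15 (1.23 ± 0.13, adjusted p = 2.04e-14), Dppa3 (1.63 ± 0.30) and Gm20767 (3.08 ± 0.52) rose more in B10 than in C2. Otx2 went from 39.33 ± 6.4 to 19.77 ± 4.87 CPM in B10 and from 13.07 ± 1.16 to 26.66 ± 3.39 CPM in C2 (−2.01 ± 0.33). Of 14 2-cell-like genes 7 rose more in B10 (7 and 0 adjusted over the list alone). Between A12 and C3 57 genes were higher and 7 lower, and between B10 and C2 70 and 20. Between A8 and B11 edgeR and DESeq2 called 0 genes, with 527 at unadjusted p < 0.05, and 2 were called without the low-count filter. The 64 calls of A12 and C3 became 32, 36 or 37 without C3 48 h replicate 3, C3 48 h replicate 2 or A12 0 h replicate 2, and 1.2e+02 when fitted alone, of which 73.9% were higher against 89.1%.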

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

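The tests of explanations and the regroupings of libraries in this part were chosen only after the results had been seen, so each pattern is a hypothesis from the data it was tested on.

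Genes of chromosomes X and 14 stood lower than wild-type in the Rybp-null line and its Suz12-degron clones. Shares and medians of chromosomes in this part cover only genes averaging at least 20 CPM. In each of those 10 groups at least 90.8% of X-linked genes lay below wild-type, which may reflect a whole-chromosome copy difference in that line. For chromosome 14 the lowest share was 71.8%, and a copy difference cannot be told apart from other causes. Scaling or library size would move other autosomes too, but their largest median was 0.11. Loss of Rybp within 48 h did not lower X-linked genes in the Rybp-degron clones (median −0.03).

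Auxin called 131 genes in Rybp-null cells and 0 in the other lines without a degron when all libraries were fitted together, but 30 in Rybp-null, 24 in wild-type, 50 in Eed-null and 17 in Ring1-null cells when each line was fitted alone. Without Rybp-null 48 h replicate 1, 81 genes were called, so that library is not the sole cause, and without 0 h replicate 2 there were 24. The called genes varied 1.21 times as much between replicates of other groups as genes of matched level, and 61.1% moved the same way in the Suz12-degron clones. Variation unrelated to auxin and an auxin response of cells without Rybp therefore cannot be told apart. The direct test of the auxin effect found 23 genes differing from wild-type, 1 from Eed-null and 84 from Ring1-null cells.

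Genes of chromosomes 6 and 8 stood higher in clone C2 than in wild-type. In the 4 groups of C2 at least 73.1% of these genes lay at or above wild-type, and a copy difference in this clone cannot be told apart from other causes. Loss of Ring1 or tagging of Rnf2 is excluded as the cause, because clone B10 of the same genotype showed at most 0.09.

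The 48 h effect differed from that of the parental line for 502 (Rybp), 702 (Suz12) and 1838 genes (Rnf2 degron). A difference of effects alone does not show whether the degron clones or the parent moved. Between genotypes the effects differed for 1236 (Rybp and Suz12), 1152 (Rybp and Rnf2) and 2229 genes (Suz12 and Rnf2). Between clones they differed for 64 (A12 and C3) and 90 genes (B10 and C2).

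Each contrast was refitted on its own libraries with their groups exchanged. With 10 possible splits there are too few for a share under 0.05. The real and the highest other counts were 751 and 0 for Eed-null, 2590 and 0 for Rybp-null and 141 and 1 for Ring1-null against wild-type. For auxin they were 24 and 2 in wild-type, 50 and 36 in Eed-null, 30 and 0 in Rybp-null and 17 and 2 in Ring1-null cells. Of 100 splits only the real 1 reached its count for Rybp degradation at 6, 24 and 48 h (61, 1329 and 2228, highest other 2, 408 and 149). The same held for Suz12 at 24 and 48 h (471 and 2015, highest other 366 and 618) and for Rnf2 at 6, 24 and 48 h (589, 2571 and 4347, highest other 128, 574 and 900). It also held beyond auxin (765, 595 and 1827, highest other 86, 27 and 0) and between genotypes (1370, 1258 and 2210, highest other 0, 412 and 13). Except between genotypes, a random division of the libraries is excluded as the source of the calls in these contrasts. Between genotypes the splits exchange libraries of different clones within each hour of auxin and treat those of the same clone as independent. There they do not exclude a chance difference between clones.

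For the combined losses 2 of 100 splits reached the real count, the real 1 included (1627 and 381, highest other 1835 and 402). Before auxin, 1, 1 and 2 of 84 splits did (725, 388 and 551, highest other 380, 188 and 732), and between A12 and C3 only the real 1 did (1.2e+02, highest other 78). The shares are under 0.05, but these splits mix libraries of different lines or clones as if independent. They therefore do not exclude a chance difference between lines or clones. For the combined losses they also exchange genotypes, so they do not test a departure from the sum. For both combined losses and for the Rnf2-degron clones before auxin 1 other division called more genes than the real 1. A random division is not excluded for Suz12 at 6 h (real 1, reached by 12 splits). Its highest other count, 206, is far above the real 1 and points to a structure among the samples that was not identified. For B10 and C2 the real count was 93, reached by 9 splits (highest other 1936). Those splits exchange libraries of both clones within each hour of auxin, so a lasting difference between the clones can enter their counts. They therefore cannot decide about chance there. For A8 and B11 the real count was 0, which all 100 splits reach by definition, so the splits say nothing about chance there (highest other 327).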

How the results depend on the processing

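All alternatives were set before the data were examined, except that leaving out multimapping reads, chromosomes 6, 8, 14 and X, both doubted libraries, or the deleted gene of a subunit list was chosen only after results had been seen.

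Each group held 3 libraries and each null genotype 1 line, and the labels do not give the origin of cultures. The cause of the differences in this part was not tested. Replicate numbers did not pair the samples: libraries of the same number correlated at −0.0086 within a line (range −0.166 to 0.126), and a replicate block moved the auxin calls of Rybp-null cells to 86. It moved no other count of calls by more than 1.5 times. Named genes kept direction and call in 25120 comparisons with an alternative, lost the call in 1883 and turned direction in 15.

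DESeq2 gave 84 calls for Rybp degradation at 6 h and 2 for Suz12 at 6 h. Without the low-count filter auxin gave 2 calls in wild-type, 5 in Eed-null and 205 in Rybp-null cells, and A8 against B11 gave 2. Fitted alone, auxin gave 24 (wild-type), 50 (Eed-null), 30 (Rybp-null) and 17 (Ring1-null) calls, Rybp degradation at 6 h 61 and Suz12 at 6 and 24 h 1 and 471. In the same setting the Rybp degron beyond auxin gave 765, its clones before auxin 725 and A12 against C3 1.2e+02. Without both doubted libraries the auxin calls of Rybp-null cells were 78. Without chromosomes 6, 8, 14 and X, Ring1-null against wild-type gave 79, Suz12 at 6 h 1 and the Rnf2-degron clones before auxin 359.

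Single clones called fewer genes for the most part. A12 gave 698 and 842 at 24 and 48 h and 211 beyond auxin, and C3 gave 18, 381 and 1314 at 6, 24 and 48 h. A8 gave 1, 346 and 1107, and 463 before auxin. B11 gave 2, 196 and 1159, 418 beyond auxin and 92 before it. B10 gave 431 and 2921 at 6 and 48 h and 278 before auxin, and C2 gave 320 and 1696 at 6 and 24 h and 1004 before it.

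With 1 library left out, counts ran from 338 to 483 for Eed-null against wild-type, 24 to 162 for auxin in Rybp-null cells and 83 to 285 for Rybp degradation at 6 h. They ran from 451 to 689 for the Suz12 degron beyond auxin and 271 to 471 for its combined loss. Before auxin they ran from 278 to 465 (Rybp), 82 to 316 (Suz12) and 321 to 518 (Rnf2 degron), and for A12 against C3 from 32 to 93. At 2-fold or more, genotypes shared 74 higher and 12 lower genes (Rybp and Suz12), 214 and 73 (Rybp and Rnf2) and 209 and 24 (Suz12 and Rnf2).

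Directions turned for few genes. Before auxin Rybp was 0.14 in A12 alone. Cdkn2d at 48 h of Rnf2 degradation was −0.01 in C2 alone. With single nulls at 0 h, Six2 was −0.39 in the Rybp-degron combined loss, and Sox3 and Rps3 were −0.14 and −0.15 in that of Suz12. Ribosomal protein genes turned with reads not multimapping. Rpl24 and Rps6 were 0.11 and 0.10 in Rybp-null cells, Rpl15 and Rpl5 0.36 and 0.07 at 48 h of Rybp degradation, Rpl24 0.11 at 24 h and Rps16 0.01 at 48 h of Rnf2 degradation. Rps16 was 0.03 in the Suz12 combined loss, Rpl15 0.19 in Rnf2-degron clones before auxin, Rpl15 0.16 between the Rybp and Suz12 effects and Rps16 −0.03 between those of Suz12 and Rnf2.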

Other observations

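No test of an explanation was made for this part, and its genes were picked only after their values were seen. The calls given here for Ccnd2 and Trh were not put through the alternative analyses. Ccnd2, a G1 cyclin gene, stood at 106.6 ± 11.1 CPM in wild-type, 407.6 ± 35.6 in Eed-null and 10.31 ± 2.21 CPM in Rybp-null cells (log2 1.92, adjusted p = 1.54e-29, and −3.37, adjusted p = 5.51e-30). Suz12 degradation in Rybp-null cells raised it by 2.43 at 24 h and 2.28 at 48 h, and Rybp degradation in Eed-null cells changed it by −0.96 and −1.44. In these lines its level was higher after loss of Eed or Suz12 and lower after each loss of Rybp, a pattern noticed in these data and not tested on others. Ccnd2 was also lower in Ring1-null cells, as given above, so a lower level was not particular to loss of Rybp.

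Trh, the thyrotropin-releasing hormone gene, was lower in all 3 null lines than in wild-type cells (log2 −1.17 in Eed-null, −1.72 in Rybp-null and −0.56 in Ring1-null cells, edgeR adjusted p = 1.31e-13, 2.21e-23 and 0.00099). It changed by −1.63 at 48 h of Rybp degradation and by −0.54 at 48 h of Suz12 degradation.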
